A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

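Expression was measured on 17 Affymetrix Yeast Genome 2.0 arrays from 3 Saccharomyces cerevisiae strains of the BY4742 background, a laboratory haploid of mating type alpha: the wild type, a strain overexpressing FLO1, and a strain labelled BY4742::FLO8. Per the labels, cells were loaded in saline, medium was injected 5 days after launch, and cultures grew for 72 h at 23 °C on the International Space Station before they were filtered and fixed in RNAlater. The ground cultures were grown after the flight in an incubator that followed the temperatures logged in orbit. Groups were taken from the titles of the samples. Each strain had 3 ground and 3 flight arrays, except the FLO1 overexpression strain, which had 2 flight arrays. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples. Flight and ground cultures were grown at different times, so batch and condition cannot be told apart.

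The deposited values are log2 probe set levels. The submitters' processing notes name RMA, the R package affy 1.26.1 and MAS5; the role of MAS5 is not stated. The values ran from 2.58 to 15.08 log2, and the medians over S. cerevisiae probe sets lay between 9.84 and 9.94 in all arrays, so no further normalization was applied. A small shift with condition remained: ground medians reached at most 9.90, and of the flight arrays only FLO8 microgravity replicate 3 (9.88) lay among them. Median centring, an alternative below, removes it. Pearson correlations between arrays ran from 0.977 to 0.9985, and 0 pairs of arrays were identical. No scanner files were available, so background correction could not be redone.

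The table holds 10928 probe sets. Of these, 7244 carry 1 gene symbol, 1 carries several and the others carry none. By organism, 5498 are annotated to S. cerevisiae, 1747 to S. pombe, 166 are controls and 3517 have no gene name; 12 symbols were updated to current names. For the 47 genes with several probe sets 1 was kept, which left 5449 genes for testing. The 95th percentile of the S. pombe probe sets, 4.56 log2, served as the level of background signal, and 58 of the genes tested had a mean below it. The build behind the array design is not named, so no coordinates are given. Genes with close relatives, such as the paired ribosomal protein genes, the seripauperin family, and FLO1 with FLO9, can cross-hybridise, so the signal of 1 member can include another. The number of arrays limits the precision of each value.

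Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 17 arrays, so that the 6 groups share 1 estimate of spread per gene (11 residual degrees of freedom). Moderated statistics came from eBayes without trend, and p-values were adjusted by the Benjamini-Hochberg method over all 5449 genes within a comparison. A gene was called changed at an adjusted p under 0.05, and all tests were two-sided. The 10 planned comparisons were microgravity against ground within each strain, each engineered strain against wild type on the ground and in flight, and the difference in flight response between each pair of strains. The average flight difference over the 3 strains was added after the data were examined. Errors of levels are standard deviations (SD) and errors of differences are standard errors (SE).

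Gene groups were 45 lists written before the data were examined. Each was tested against the remaining genes with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; p-values were adjusted over the lists within a comparison. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes. Counts of list members that changed are given as adjusted over all genes and as adjusted over the list alone. An exact permutation of flight and ground labels within strains (4000 assignments, smallest possible p 2.50e-04) was added after the data were examined, for the list means averaged over strains.

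Genes were named by a rule written before the data were examined, which took the FLO genes in every group, up to 8 called genes per direction for each flight comparison and up to 5 for each strain comparison, ranked by log2 fold change. These genes had to lie above background. For flight within a strain, and for strains compared within a condition, the arrays of the groups compared also could not overlap. No overlap rule was applied to the average over strains, so genes named for it need not separate flight from ground arrays. Where none passed, the 3 genes with the lowest p are named as not passing. For each list described, up to 4 members with the lowest p are named. FLO5 has no probe set of its own name on the array.

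RNA quality was read from the difference between 3 prime and 5 prime probe sets of 7 control genes on each array, and signal outside the target organism from the median of the S. pombe probe sets. Both were compared between flight and ground by exact permutation. With 3 against 3 arrays the smallest exact p is 0.1, so these tests within a strain cannot fall below 0.05.

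The pipeline was tested on simulated data of the same size, in which 200 of 5449 genes were changed. For a flight comparison within a strain it recovered 53.0% to 67.0% of genes changed by 1 log2 unit and 88.0% to 95.0% of those changed by 2. False calls made up 4.7% to 7.2% of the calls. For the average over strains, recovery at 1 log2 unit was 87.0%, and for a difference in response between strains it was 27.0%. The camera test called a list shifted by 0.3 log2 in 20 of 20 simulated runs and 0 of 880 other lists. The simulated genes varied independently of each other and by the same amount in all groups. These rates therefore do not show how often lists of correlated genes are called falsely, or what a wider spread in flight does.

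The alternatives were a filter on dim probe sets, a floor on dim values, all S. cerevisiae probe sets, quantile normalization within S. cerevisiae, median centring, eBayes with trend and robust, array weights, a fit of only the groups compared, the replicate number as a block, the 3 prime minus 5 prime difference as a covariate, an absolute log2 fold change of at least 1, and leaving out each array. Leaving out 4 flight arrays together was added after the data were examined. No columns were left out. The study's integration with protein interaction networks was not repeated, because no network was available.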

Results

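On the ground and in flight alike, FLO1 was called higher than in wild type in the FLO1 overexpression strain, and FLO11 in the strain labelled FLO8. FLO1 (YAR050W), a lectin-like cell surface protein that binds cells into flocs, read 12.70 ± 0.19 log2 (SD, n = 3) on the ground in the FLO1 strain, against 8.47 ± 0.27 in wild type (n = 3). FLO11 (YIR019C), a flocculin of adhesion and filamentous growth, read 12.17 ± 0.81 (n = 3) in the strain labelled FLO8, against 8.57 ± 0.10 in wild type. FLO10 (YKR102W), a related flocculin, lay between 9.43 and 9.95 in all 6 group means. No flocculation gene passed the test for microgravity against ground in any strain. For FLO1 the flight differences were −0.01, −0.16 and −0.22 log2 in wild type, the FLO1 strain and the strain labelled FLO8, where the arrays of a flight group varied by up to 0.86 (SD).

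**Figure D1:**
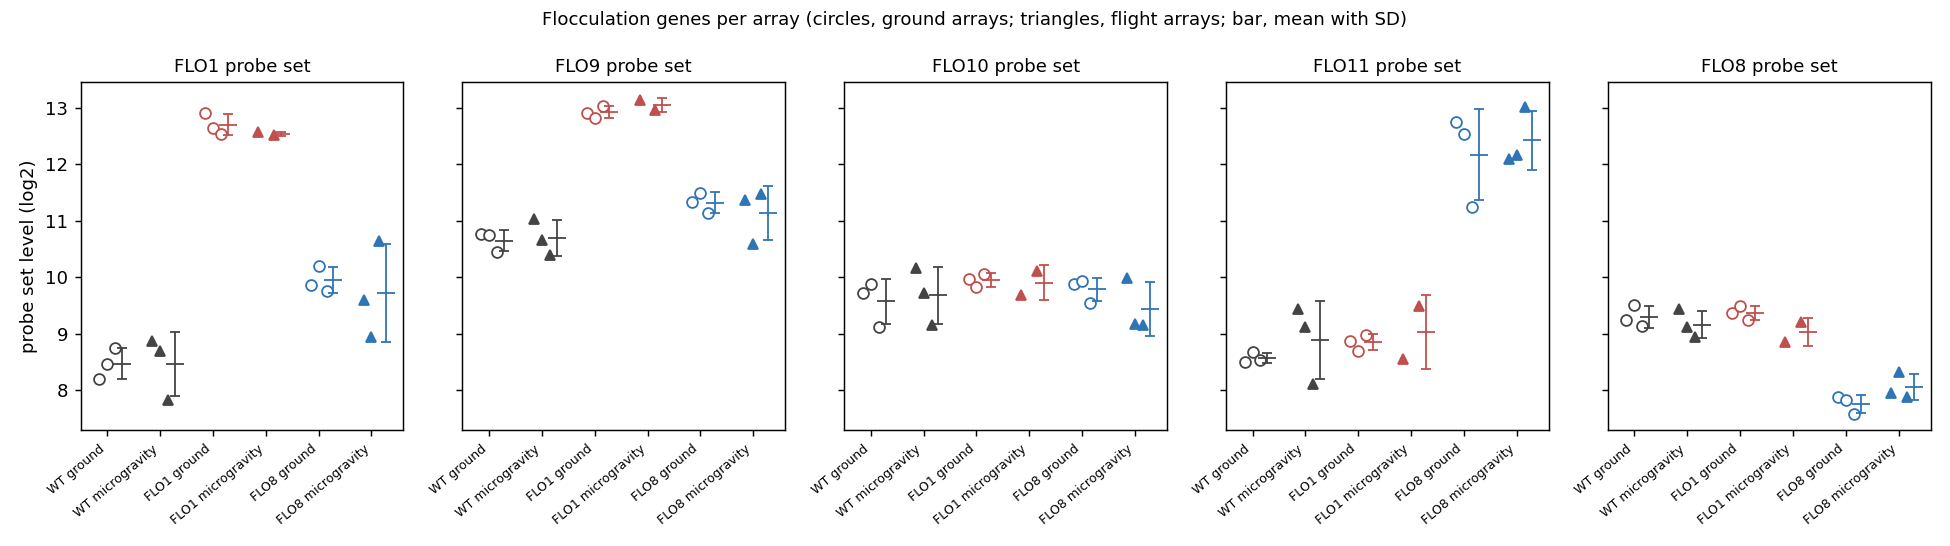
Level of 5 flocculation gene probe sets (vertical axis, log2) on each of the 17 arrays by strain and condition; circles are ground arrays, triangles are flight arrays, and bars are group means with SD. FLO1 and FLO9 are highest in the FLO1 strain, and FLO11 is highest in the strain labelled FLO8, whose FLO8 probe set reads at most 8.31 against at least 8.85 elsewhere.

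In the FLO1 overexpression strain, FLO1 was 18.8-fold higher than in wild type on the ground (log2 difference 4.23, SE 0.35, adjusted p = 3.97e-05, 3 against 3 arrays). FLO9 (YAL063C), a flocculin closely related to FLO1, was 4.84-fold higher (2.27, SE 0.22, adjusted p = 1.51e-04). These were the 2 genes called on the ground, and the same 2 were called in flight. There FLO1 was higher by 4.08 (SE 0.39, adjusted p = 2.67e-04) and FLO9 by 2.36 (SE 0.25, adjusted p = 3.94e-04, 2 against 3 arrays). In flight FLO9 lost its call in 1 of 11 alternatives. At an unadjusted p under 0.05 there were 75 genes on the ground and 423 in flight, where chance gives 272.4. Arrays of this strain lay 0.132 log2 (root mean square) from their group mean on the ground and 0.497 in flight. Because all groups share 1 estimate of spread, ground p-values tend to be too large and flight p-values too small. The counts on the ground and in flight therefore cannot be compared, and ground changes can be missed. With array weights 501 genes were called on the ground. The FLO9 probe set is of a kind that can read several related genes, so its rise can include FLO1 transcripts.

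Of the 8 flocculins and adhesins measured, 2 rose in the FLO1 strain on the ground, both adjusted over all genes and adjusted over the list alone. The list was called higher (mean 1.00, adjusted p = 0.174 with an estimated correlation). The 2 that rose were the overexpressed FLO1 itself and FLO9, so the call says little about the other adhesins. The 25 mating pheromone genes were also called higher on the ground, with a mean of 0.24 and 18 members above 0 (adjusted p = 0.174 with an estimated correlation). Adjusted over the list alone 2 of them rose, and adjusted over all genes 0 did by limma. PRM2 and PRM6, pheromone-regulated membrane proteins, differed by 0.67 (SE 0.17) and 0.61 (SE 0.16), each at an adjusted p of 1.00 over all genes. Ribosome biogenesis genes were called lower on the ground, with a mean of −0.35 and 57 of 61 members below 0 (adjusted p = 0.638 with an estimated correlation), and 0 members passed either adjustment by limma. Without WT ground replicate 3 that mean was −0.57.

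In flight, the PAU and ergosterol lists were called higher in the FLO1 strain than in wild type, though neither with an estimated correlation. All 13 seripauperin (PAU) genes, a family of cell wall mannoproteins expressed in anaerobic growth, were above wild type, with a list mean of 1.86. Adjusted over the list alone 13 rose, and adjusted over all genes 0 did by limma (adjusted p = 0.162 with an estimated correlation). Of 27 ergosterol synthesis genes, 25 were above wild type, with a mean of 0.63 (adjusted p = 0.162 with an estimated correlation). PST1, a cell wall protein of the integrity pathway, differed by 2.11 (SE 0.56, adjusted p = 0.367). These values leaned on FLO1 microgravity replicate 1: without it the PAU mean was 0.48 and the ergosterol mean 0.20, and both lists kept their call. With the 3 prime minus 5 prime covariate the PAU mean was 1.15, still called. Without FLO1 microgravity replicate 2, 396 genes were called in place of 2, with the lone remaining flight array of the strain assumed to vary like the other groups.

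In the strain labelled FLO8, FLO11 rose 12.2-fold on the ground (3.61, SE 0.40, adjusted p = 0.00110) and 11.6-fold in flight (3.54, SE 0.40, adjusted p = 0.00216; 3 against 3 arrays each). The probe set of FLO8 (YER109C), which encodes a transcription factor that activates FLO11 and FLO1, read lower by 1.54 log2 on the ground (SE 0.18, adjusted p = 0.00110). In flight it read lower by 1.11 (SE 0.18, adjusted p = 0.0460). Probe set levels do not show whether either strain makes an active FLO8 protein. FLO1 differed by 1.48 on the ground (SE 0.35, adjusted p = 0.689) and read 9.72 ± 0.86 in flight against 8.46 ± 0.57 in wild type (adjusted p = 0.205), which did not pass over all genes. AGA2, the binding subunit of a-agglutinin, differed by −1.25 on the ground (SE 0.30, adjusted p = 0.689). FLO11 and FLO8 were the 2 genes called in each condition, and 194 genes on the ground and 544 in flight had an unadjusted p under 0.05. The spread shared by ground and flight groups limits these counts as it does those of the FLO1 strain. Arrays of the strain labelled FLO8 lay 0.169 log2 (root mean square) from their group mean on the ground and 0.548 in flight. Ground p-values thus tend to be too large and flight p-values too small, so the counts cannot be compared.

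Among the 8 flocculins and adhesins, 3 rose and 1 fell in the strain labelled FLO8 on the ground when adjusted over the list alone, against 1 and 0 adjusted over all genes, and the list was called higher (mean 0.61; adjusted p = 0.688 with an estimated correlation). In flight 2 rose when adjusted over the list alone and 1 over all genes (mean 0.87, adjusted p = 0.30 with an estimated correlation). The 1 that rose over all genes in each condition was FLO11, so both list means lean on it. Also in flight, 22 of 24 genes of the glyoxylate cycle and gluconeogenesis, which let cells grow on ethanol and acetate, lay below wild type, with a mean of −0.79 (adjusted p = 0.30 with an estimated correlation). The mean was −0.39 without FLO8 microgravity replicate 2 and −1.17 without replicate 3. Their members with the lowest p were CRC1, a mitochondrial carnitine carrier, at −1.12 (SE 0.36, adjusted p = 0.303) and YAT1, a carnitine acetyltransferase, at −0.78 (SE 0.27, adjusted p = 0.348). Fry called 6 lists in this comparison, among them histones (mean −0.31, fry adjusted p = 0.0236; 0.221 with an estimated correlation in camera) and the subtelomeric COS family (mean 0.43, fry adjusted p = 0.0236; adjusted p = 0.189 with an estimated correlation). HHT1, a histone H3 gene, differed by −0.69 (SE 0.14, adjusted p = 0.0925), and COS12 by 1.67 (SE 0.30, adjusted p = 0.0647).

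The ground calls of FLO11 and FLO8 held in all 11 alternatives and without each of the 6 arrays in turn. In flight FLO11 lost its call in 2 of 11 alternatives and FLO8 in 4. FLO8 also lost it there without 4 of 6 single arrays, with adjusted p up to 0.184. With array weights 645 genes were called on the ground and 13 in flight. Of the 17 arrays 4 stand apart, which are WT microgravity replicate 3, FLO1 microgravity replicate 1 and FLO8 microgravity replicates 2 and 3. Leaving these 4 out keeps 1 flight array in the FLO1 strain and 1 in the strain labelled FLO8, each assumed to vary like the other groups. Limma then called 20 genes on the ground and 0 in flight for the strain labelled FLO8 against wild type. Leaving out single arrays gave, in flight, 1 gene (WT microgravity replicate 1, 2 or 3, or FLO8 microgravity replicate 3), 4 (FLO8 microgravity replicate 2) or 32 (FLO8 microgravity replicate 1).

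In wild type, microgravity came with lower ribosomal protein transcripts. Of the 8 genes called, all lower in flight, 7 encode proteins of the cytosolic ribosome (3 against 3 arrays). These proteins are made together in growing cells. RPS22A (YJL190C) fell by 1.46 on the log2 scale (SE 0.15, adjusted p = 7.97e-04), RPL31B (YLR406C) by 1.48 (SE 0.20, adjusted p = 0.00638) and RPS1B (YML063W) by 1.65 (SE 0.29, adjusted p = 0.0355). RPL12A, RPS26B, RPL17B and RPL9A fell by 0.99 to 1.44, at adjusted p from 0.0112 to 0.0353. The eighth gene was ELO2 (YCR034W), a fatty acid elongase that makes the very long chains of sphingolipids, which fell by 1.03 (SE 0.17, adjusted p = 0.0274). At an unadjusted p under 0.05 there were 545 genes.

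Over the whole list of 128 ribosomal proteins in wild type, 120 lay below 0, with a median of −0.76 log2. Adjusted over all genes 7 fell, and adjusted over the list alone 75 did (adjusted p = 0.325 with an estimated correlation). Of 24 genes of the glyoxylate cycle and gluconeogenesis 22 were above 0, with a mean of 0.64, and none passed either adjustment by limma (adjusted p = 0.716 with an estimated correlation). ICL1, isocitrate lyase of the glyoxylate cycle, differed by 2.23 (SE 0.74, adjusted p = 0.251), and ADH2, the alcohol dehydrogenase that oxidises ethanol, by 1.39 (SE 0.37, adjusted p = 0.187). Multidrug and weak acid transporters were called higher as a list (mean 0.36, 19 of 24 above 0; adjusted p = 0.325 with an estimated correlation); 3 rose when adjusted over the list alone and 0 over all genes. PDR5, a drug efflux pump, differed by 1.73 (SE 0.49, adjusted p = 0.191). Without WT ground replicate 3 the call of that list ended (0.27). Cell wall genes were called lower (mean −0.23, 29 of 42 below 0; adjusted p = 0.325 with an estimated correlation), with EGT2, a glycoprotein of mother and daughter separation, at −0.98 (SE 0.21, adjusted p = 0.102); 2 members fell when adjusted over the list alone and 0 over all genes. Of the 34 proteasome genes, 30 were above 0 (mean 0.19; adjusted p = 0.716 with an estimated correlation), and their call ended without WT ground replicate 2 (0.11) or WT microgravity replicate 2 (0.15).

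The wild-type count depended on the fit and on single arrays. It was 0 with only the arrays compared, 1 with the 3 prime minus 5 prime covariate, 3 with the replicate number as a block, 13 with median centring and 598 with array weights. The 3 prime minus 5 prime difference itself was 1.18 ± 0.02 (SD, n = 3) in flight and 1.09 ± 0.05 (n = 3) on the ground (exact p = 0.1, the smallest possible here). The count was 1 without WT ground replicate 1 or 2, 2 without WT microgravity replicate 2, 4 without WT microgravity replicate 3, 5 without WT microgravity replicate 1 and 14 without WT ground replicate 3. Of the 4 arrays that stand apart, only WT microgravity replicate 3 is a wild-type array. Without all 4, the count rose far above that without replicate 3 alone. The spread shared by all groups then came mostly from ground arrays. That rise therefore cannot be read as flight changes in wild type that 1 array had hidden.

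In the FLO1 overexpression strain, 2 genes changed, both lower in flight (2 flight against 3 ground arrays). CLN1 (YMR199W), a cyclin that drives cells from G1 into S phase, fell by 1.30 on the log2 scale (SE 0.21, adjusted p = 0.0485), and RPS22A fell by 1.19 (SE 0.17, adjusted p = 0.0349). At an unadjusted p under 0.05 there were 714 genes. Ribosomal proteins lay below 0 in 125 of 128 cases, with a median of −0.40. Adjusted over the list alone 4 fell, and over all genes 1 did (adjusted p = 0.470 with an estimated correlation). Proteasome genes were above 0 in 28 of 34 cases, with a median of 0.37, and 2 rose adjusted over the list alone (adjusted p = 0.327 with an estimated correlation). Both calls ended without FLO1 microgravity replicate 2, where the means were −0.16 and 0.20 in place of −0.44 and 0.29, and the ribosomal protein mean was −0.72 without replicate 1.

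The largest shift among the lists called in this strain was in the PAU family, whose 13 members were all above ground, with a median of 1.83. Adjusted over the list alone 13 rose, and over all genes 0 did by limma (adjusted p = 0.322 with an estimated correlation). PAU24 differed by 3.03 (SE 0.63, adjusted p = 0.166) and PAU2 by 3.13 (SE 0.76, adjusted p = 0.169). Of the 25 hypoxic and anaerobic genes, 12 rose when adjusted over the list alone (adjusted p = 0.322 with an estimated correlation). Among the 25, HEM13, a heme synthesis enzyme repressed by oxygen, differed by 1.65 (SE 0.37, adjusted p = 0.169 over all genes), and DAN1, an anaerobic mannoprotein, by 2.96 (SE 0.74, adjusted p = 0.169 over all genes). Ergosterol genes were above 0 in 24 of 27 cases (mean 0.52; adjusted p = 0.323 with an estimated correlation). ERG5, a sterol desaturase, differed by 1.48 (SE 0.44, adjusted p = 0.198) and UPC2, the sterol-sensing activator, by 1.71 (SE 0.53, adjusted p = 0.218). The cell wall integrity list was called higher (mean 0.26; adjusted p = 0.322 with an estimated correlation), and 4 members rose when adjusted over the list alone. PST1 differed by 1.84 (SE 0.56, adjusted p = 0.202).

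The flight arrays of this strain differed from each other. The PAU mean was 14.04 log2 on FLO1 microgravity replicate 1 and 11.28 on replicate 2, against 10.73 ± 0.09 (SD, n = 3) on the ground. Without FLO1 microgravity replicate 1 the list means were 0.55 for PAU, 0.37 for hypoxic genes and 0.093 for ergosterol, whose call ended. The call of the cell wall integrity list ended without replicate 1 (0.16) or 2 (0.35). With the 3 prime minus 5 prime difference, a measure of RNA quality, as a covariate the calls of all 4 lists ended, with means of 0.72 for PAU (adjusted p = 0.0885), 0.52 for hypoxic genes (adjusted p = 0.178), 0.28 for ergosterol (adjusted p = 0.155) and 0.14 for cell wall integrity (adjusted p = 0.760). Limma called 510 genes without replicate 2, 307 higher and 203 lower, and 0 without replicate 1 or any 1 of the 3 ground arrays. Without the 4 arrays that stand apart it called 5 genes, 1 of the 2 among them, and it called 0 with array weights, the block, the covariate or only the arrays compared. The 3 prime minus 5 prime difference was 1.34 ± 0.11 (n = 2) in this flight group and 1.08 ± 0.07 (n = 3) on the ground (exact p = 0.1).

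**Figure D2:**
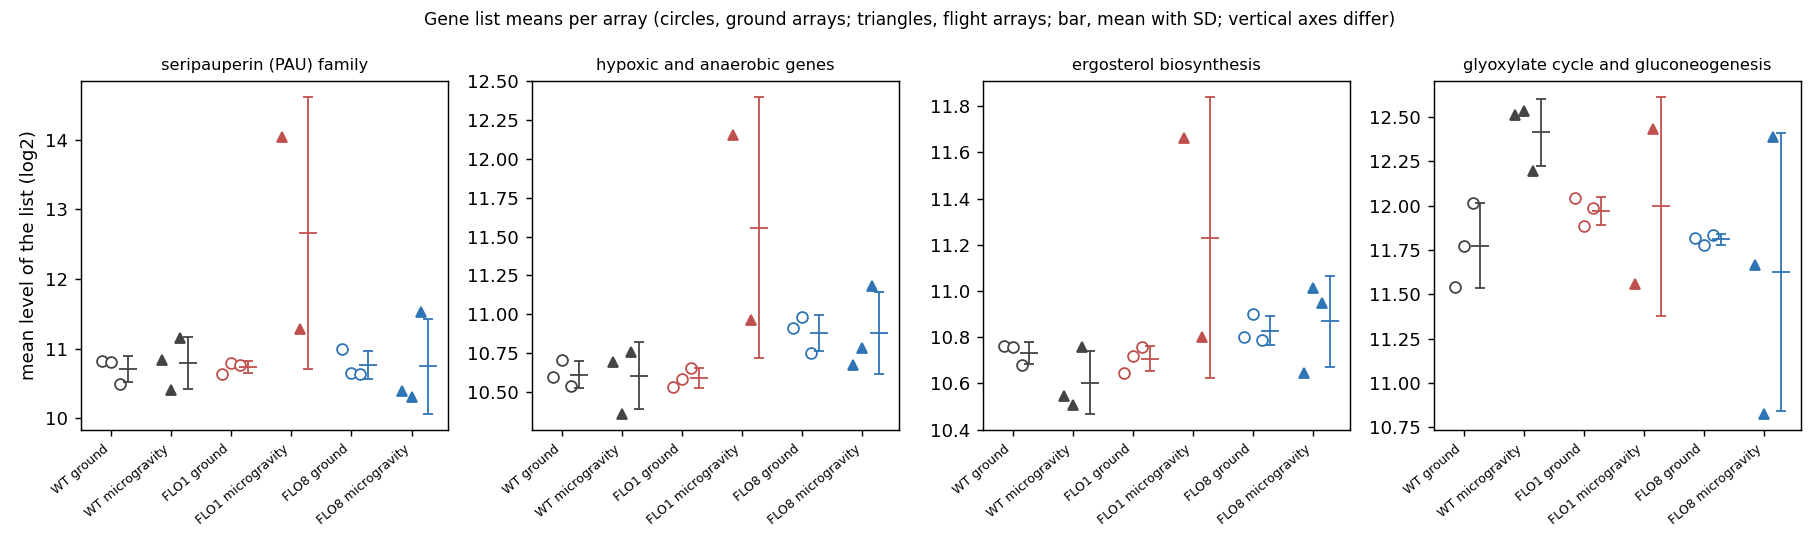
Mean log2 level of 4 gene lists (vertical axes, which differ between panels) on each array by strain and condition; circles are ground arrays, triangles are flight arrays, and bars are group means with SD. FLO1 microgravity replicate 1 reads 14.04 for the PAU family, above all 16 other arrays.

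In the strain labelled FLO8, 0 genes passed the limma test for microgravity against ground (3 against 3 arrays), and 357 had an unadjusted p under 0.05. With array weights 748 were called, 315 higher and 433 lower, so the 0 depends on how the arrays are weighted. The weights were 2.66, 0.087 and 0.27 for FLO8 microgravity replicates 1, 2 and 3, and 8.35 for FLO8 ground replicate 2. Each of these weighted means rests mostly on 1 array, so the 748 is not a better count. The 3 genes with the lowest p were YBL100W-A, a retrotransposon Gag gene, at −1.53 (SE 0.24, adjusted p = 0.0930), CLN1 at −0.86 (SE 0.18, adjusted p = 0.672) and CLN2, its partner G1 cyclin, at −0.69 (SE 0.16, adjusted p = 0.672). The ribosomal protein and proteasome lists were called in this strain as in the other 2. Ribosomal proteins lay below 0 in 126 of 128 cases (median −0.41; adjusted p = 0.796 with an estimated correlation), and proteasome genes above 0 in 33 of 34 (median 0.33; adjusted p = 0.667 with an estimated correlation). Histone genes were below 0 in 9 of 9 cases (mean −0.23; adjusted p = 0.667 with an estimated correlation), with HTB2, a histone H2B gene, at −0.48 (SE 0.15, adjusted p = 0.672). Cell wall genes were called lower with a mean of −0.20 (adjusted p = 0.777 with an estimated correlation), with UTR2, a chitin transglycosylase, at −1.11 (SE 0.30, adjusted p = 0.672). None of the members of these 4 lists passed, adjusted over the list alone or over all genes. The ribosomal protein mean was −0.41, and it was −0.23 without FLO8 microgravity replicate 1 and −0.69 without replicate 2. Replicate 2 itself read 12.38 log2 for this list, above the ground arrays of the strain (at most 12.34). Leaving out FLO8 microgravity replicate 2 gave 1 called gene, and without replicate 3 the call of the cell wall list ended (−0.11).

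Averaged over the 3 strains, 235 genes changed, 126 higher and 109 lower in microgravity, and 1180 had an unadjusted p under 0.05. This average was computed after the strains had been examined separately. Of the 235, 234 moved the same way in all 3 strains, an agreement partly built in because the genes were chosen by their mean over the same strains. Ribosomal proteins made up 47 of the 109 lower genes, and 88 of 128 fell when adjusted over the list alone. In all, 127 lay below 0, with a median of −0.52 (adjusted p = 0.431 with an estimated correlation). RPS22A fell by 1.09 (SE 0.09, adjusted p = 4.90e-05), RPL12A by 0.89 (SE 0.09, adjusted p = 3.25e-04) and RPL22A by 1.06 (SE 0.19, adjusted p = 0.00974). The exact permutation of this list mean gave p = 0.00425 and an adjusted p of 0.0563 over the 45 lists.

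Proteasome genes moved the other way. Of 34 members, 7 rose adjusted over all genes. Adjusted over the list alone, 19 rose and 1 fell (median 0.32; adjusted p = 0.431 with an estimated correlation). PRE4 (YFR050C) and PRE10 (YOR362C), subunits of the catalytic core, rose by 0.63 (SE 0.12, adjusted p = 0.0131) and 0.39 (SE 0.07, adjusted p = 0.0153), and RPT2 and RPN1 of the regulatory particle by 0.40 (SE 0.09, adjusted p = 0.0245) and 0.42 (SE 0.10, adjusted p = 0.0304). By exact permutation the proteasome was the 1 list of 45 that passed (p = 5.00e-04, adjusted p = 0.0225). UFD4, a ubiquitin ligase, rose by 0.67 (SE 0.16, adjusted p = 0.0352), and VMS1, a partner of Cdc48 in protein quality control, by 0.71 (SE 0.14, adjusted p = 0.0190). UFD4 lost its call without 12 of the 17 arrays left out in turn, RPN1 without 9, RPT2 without 8, VMS1 without 1, and PRE4 and PRE10 kept theirs without each.

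**Figure D3:**
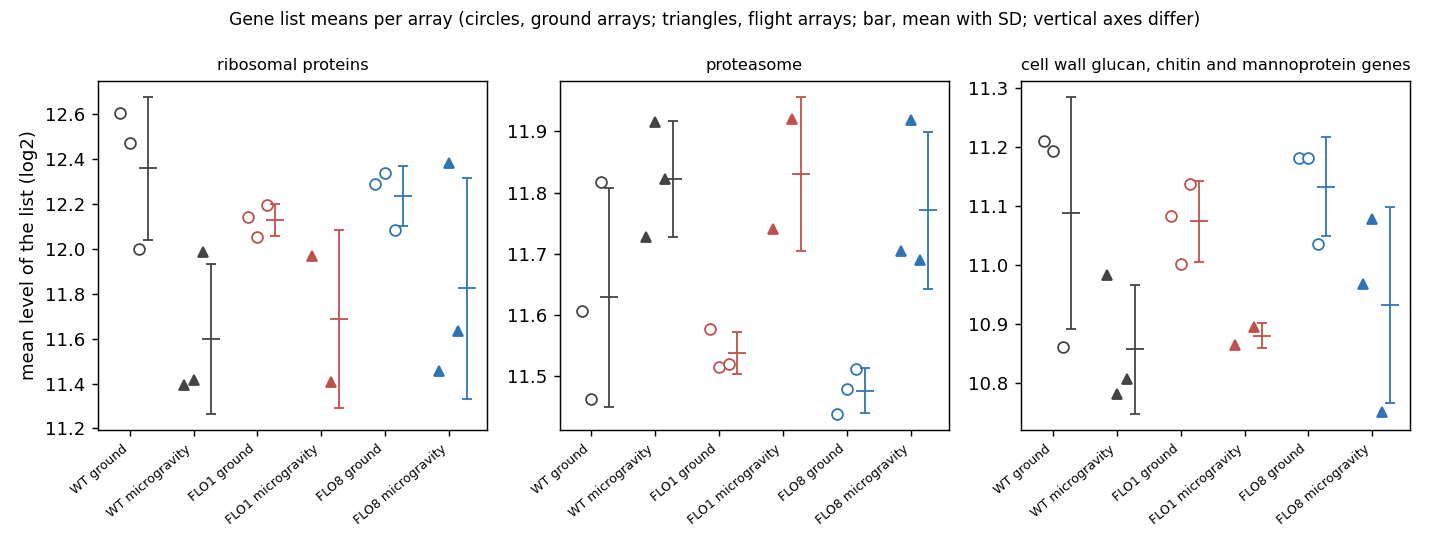
Mean log2 level of 3 gene lists (vertical axes, which differ between panels) on each array by strain and condition; circles are ground arrays, triangles are flight arrays, and bars are group means with SD. The flight mean of the 128 ribosomal proteins is lower in each strain, at 11.60, 11.69 and 11.82 against 12.36, 12.13 and 12.24 on the ground, and the flight mean of the proteasome list is higher in each.

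Some G1 genes and cell wall genes were also among those that fell in the average over strains. The G1 cyclins CLN1 and PCL1 fell by 1.04 (SE 0.11, adjusted p = 3.25e-04) and 1.27 (SE 0.30, adjusted p = 0.0332), and RNR1, the large subunit of ribonucleotide reductase, by 1.08 (SE 0.25, adjusted p = 0.0332). No array ended the call of CLN1 when left out, but PCL1 lost its call without 10 of the 17 arrays and RNR1 without 11. The list of DNA replication and S phase was not called (mean −0.028, exact permutation p = 0.795), nor was that of mitosis and G2/M (mean −0.054, exact permutation p = 0.362). Of 42 cell wall genes 6 fell adjusted over all genes and 9 adjusted over the list alone (mean −0.21; adjusted p = 0.431 with an estimated correlation; exact permutation p = 0.00400, adjusted 0.0563). UTR2 fell by 1.10 (SE 0.18, adjusted p = 0.00608), EGT2 by 0.78 (SE 0.12, adjusted p = 0.00547), GAS1, a glucan remodelling enzyme, by 0.93 (SE 0.19, adjusted p = 0.0224), and SCW11, a glucanase-like protein of daughter cell separation, by 0.85 (SE 0.20, adjusted p = 0.0332). GAS1 lost its call without 8 single arrays, SCW11 without 10, and UTR2 and EGT2 kept theirs without each of the 17. The elongases ELO2 and ELO3 fell by 0.70 (SE 0.10, adjusted p = 0.00249) and 0.69 (SE 0.15, adjusted p = 0.0252), and 7 single arrays ended the call of ELO3. They were the 2 of 25 genes of fatty acid and phospholipid synthesis that passed either adjustment, and the list was called lower (mean −0.13; adjusted p = 0.456 with an estimated correlation). Its call ended without WT microgravity replicate 2 (−0.11), FLO1 microgravity replicate 1 (−0.10) or FLO8 microgravity replicate 1 (−0.11). YBL100W-A fell by 1.20 (SE 0.15, adjusted p = 7.21e-04).

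Among the genes that rose, IZH2 (YOL002C), a membrane protein of zinc homeostasis, was higher by 1.51 (SE 0.37, adjusted p = 0.0373), ADH2 by 0.97 (SE 0.23, adjusted p = 0.0325) and MIA40, the import receptor of the mitochondrial intermembrane space, by 0.79 (SE 0.14, adjusted p = 0.00926). Of the 17 arrays left out in turn, 10 ended the call of IZH2, 8 that of ADH2 and 0 that of MIA40. Without the 4 arrays that stand apart IZH2 was higher by 0.60 and did not pass. HOP1, a protein of meiotic chromosomes, rose by 0.70 (SE 0.09, adjusted p = 0.00171), at 7.52 to 7.73 log2 in the ground groups and 8.17 to 8.60 in the flight groups. Of 32 DNA damage genes 25 were above 0 (mean 0.15; adjusted p = 0.477 with an estimated correlation). MEC1, a checkpoint kinase, rose by 0.38 (SE 0.09, adjusted p = 0.0334; call lost without 8 single arrays), and 3 genes rose when adjusted over the list alone. Without FLO1 microgravity replicate 1 that list's call ended (0.098).

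RNA quality differed between the same groups. The 3 prime minus 5 prime difference was 1.10 ± 0.06 (SD, n = 9) on ground arrays and 1.22 ± 0.09 (n = 8) on flight arrays, a difference of 0.123 (exact permutation within strains, p = 0.00225). With it as a covariate 0 of the 235 genes were called by limma and 427 genes had an unadjusted p under 0.05. The median absolute log2 fold change of the 235 went from 0.52 to 0.49 and their median SE from 0.11 to 0.19. Counts without single arrays ran from 56 (without FLO1 ground replicate 1) to 512 (without FLO1 microgravity replicate 2), with 61 to 88 without FLO1 ground replicate 2 or 3, any FLO8 ground array, WT ground replicate 1 or 2, or WT microgravity replicate 2, and 410 without FLO8 microgravity replicate 2. Without the 4 arrays that stand apart it was 1021, 581 higher and 440 lower, with 213 of the 235 among them, though 2 of the 3 flight groups then hold 1 array each. With array weights it was 776, and with the replicate number as a block 127. Centring each array on its median gave 60 higher and 131 lower genes in place of 126 and 109.

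No gene was shown to respond differently to flight between strains. Limma called 0 genes in each of the 3 tests of a difference in response, with 191, 161 and 184 at an unadjusted p under 0.05 and lowest adjusted p of 0.994, 0.998 and 0.999. The genes with the lowest p, none of which passed, were YBR196C-B at −0.96 (SE 0.24) for the FLO1 strain against wild type, SPS100, a spore wall protein, at 1.66 (SE 0.37) for the strain labelled FLO8 against wild type, and YHR140W at −1.80 (SE 0.48) for the FLO1 strain against the strain labelled FLO8. RPS22A was the 1 gene called in both wild type and the FLO1 strain, where 0.0029 genes would be shared by independent lists, and 0 genes were called in all 3 strains. Across the 5449 genes, which are not independent replicates, flight differences of 2 strains correlated at r = 0.40 (wild type with FLO1), 0.42 (wild type with FLO8) and 0.43 (FLO1 with FLO8), and 47.1% of genes had the same sign in all 3 strains, where chance gives 25%. Without FLO1 microgravity replicate 2, the tests that involve the FLO1 strain called 163 genes against wild type and 135 against the strain labelled FLO8.

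Flight arrays were also more scattered than ground arrays. The root mean square distance of an array from its group mean was 0.472 log2 ± 0.127 (SD, n = 8) in flight and 0.204 ± 0.096 (n = 9) on the ground, a difference of 0.269 (exact permutation within strains, p = 0.00125). Within strains the difference was 0.070 in wild type (exact p = 0.5), 0.365 in the FLO1 strain (exact p = 0.1) and 0.379 in the strain labelled FLO8 (exact p = 0.1). These permutations kept the distances from the real group means, and distances within a group depend on each other, so the p-values are only a rough guide. The first 3 principal components held 37.2%, 16.9% and 13.8% of the variance, and WT microgravity replicate 3, FLO1 microgravity replicate 1 and FLO8 microgravity replicates 2 and 3 stood apart on them. The median S. pombe probe set read 3.64 log2 on ground arrays and 3.63 on flight arrays (exact permutation p = 0.338).

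**Figure D4:**
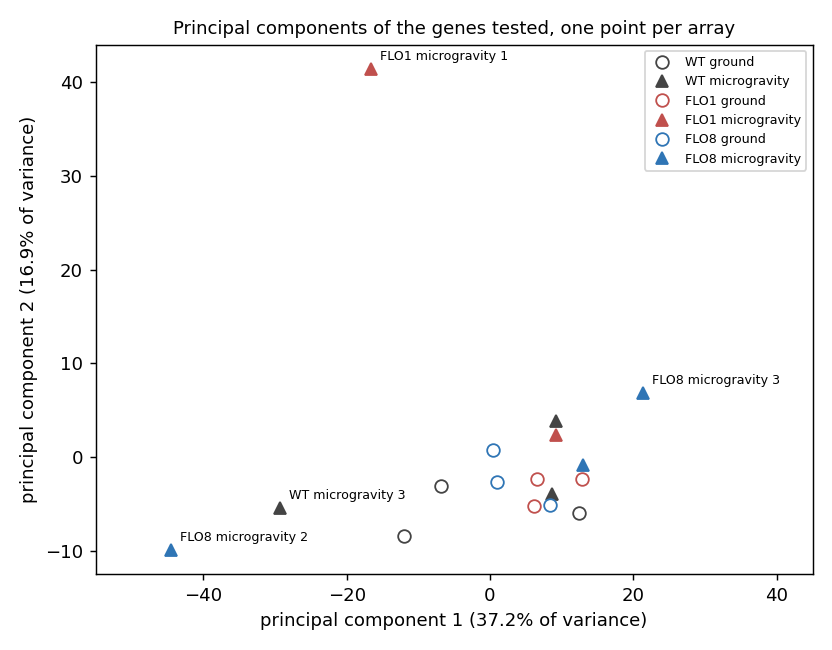
First and second principal components of the 5449 genes tested (axes, in units of the component scores), 1 point per array, with circles for ground and triangles for flight. The 4 labelled flight arrays lie away from the rest, with FLO1 microgravity replicate 1 alone at the top of the second component, which holds 16.9% of the variance.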

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

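The average over strains, the runs that leave out 1 array for the gene lists, the test of spread after correction and the 3 tests of the FLO8 probe set were chosen after the results were seen. With an estimated correlation, none of the differences between strains in the response of a list was called by camera, and fry called none, so they describe these arrays more than the strains. A lone FLO1 flight array is assumed to vary like the other groups.

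A difference between strains in the response of a gene list to flight set 26 results apart. For the FLO1 strain against wild type, 11 lists differed, and the lowest adjusted p with an estimated correlation was 0.331. The list means were 1.84 for the PAU family (13 of 13 members above 0), 0.98 for hypoxic genes, 0.65 for ergosterol synthesis, 0.50 for the zinc regulon, 0.32 for ribosomal proteins, 0.29 for methionine and sulfur assimilation and 0.24 for the cell wall integrity pathway. On the other side they were −0.61 for the glyoxylate cycle and gluconeogenesis, −0.31 for multidrug transporters, −0.26 for mitosis and −0.24 for trehalose and glycogen. The PAU, hypoxic and ergosterol lists kept their call without FLO1 microgravity replicate 1, with means of 0.46, 0.38 and 0.22. Without that array the calls of ribosomal proteins (0.038), the glyoxylate cycle (−0.18), cell wall integrity (0.14), mitosis (−0.16) and trehalose and glycogen (0.050, the opposite sign) ended. Without FLO1 microgravity replicate 2 the means were 3.22 for PAU, 1.57 for hypoxic genes, 1.08 for ergosterol, 0.60 for ribosomal proteins, −1.05 for glyoxylate and −0.54 for trehalose, and the calls of cell wall integrity (0.34), methionine (0.25), mitosis (−0.37), multidrug transporters (−0.29) and zinc (0.62) ended. Among wild-type arrays, calls ended without ground replicate 1 (multidrug −0.30), ground replicate 2 (cell wall integrity 0.22, trehalose −0.21) and ground replicate 3 (mitosis −0.17, multidrug −0.23, zinc 0.36). The same held without WT microgravity replicate 1 (mitosis −0.24, trehalose −0.22), replicate 2 (multidrug −0.24, trehalose −0.16, zinc 0.38) and replicate 3 (cell wall integrity 0.17), and without FLO1 ground replicate 2 (trehalose −0.22). The mean of ribosomal proteins was 0.20 without WT ground replicate 1, 0.50 without WT ground replicate 3 and 0.51 without WT microgravity replicate 3.

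For the strain labelled FLO8 against wild type, 5 lists differed in their response, with a lowest adjusted p of 0.484 with an estimated correlation. The means were −0.82 for the glyoxylate cycle and gluconeogenesis (21 of 24 members below 0), 0.65 for alpha-specific genes, 0.35 for ribosomal proteins (116 of 128 above 0), −0.33 for multidrug transporters and 0.19 for fatty acid and phospholipid synthesis. The ribosomal protein mean was 0.069 without FLO8 microgravity replicate 2 and 0.53 without replicate 1, and the glyoxylate mean −0.42 without replicate 2, with both calls kept. Among wild-type arrays, the ribosomal protein mean was 0.23 without ground replicate 1, 0.53 without ground replicate 3 and 0.54 without microgravity replicate 3. The call of alpha-specific genes ended without FLO8 microgravity replicate 3 (0.35), WT ground replicate 2 (0.61) or WT microgravity replicate 3 (0.55). That of fatty acid synthesis ended without FLO8 microgravity replicate 3 (0.14), WT ground replicate 2 (0.18) or WT microgravity replicate 2 (0.14).

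For the FLO1 strain against the strain labelled FLO8, 10 lists differed, with a lowest adjusted p of 0.139 with an estimated correlation. The means were 1.94 for the PAU family, 0.97 for hypoxic genes, 0.48 for ergosterol synthesis, 0.42 for thiamine and vitamin B6, 0.31 for cell wall integrity and 0.28 for DNA damage. They were −0.96 for alpha-specific genes (4 of 4 below 0), −0.46 for osmotic stress and glycerol, −0.35 for the mating pheromone response and −0.28 for fatty acid and phospholipid synthesis. The osmotic stress mean turned to 0.039 with the 3 prime minus 5 prime covariate and to 0.12 without the 4 arrays that stand apart. Without FLO1 microgravity replicate 1 the means were 0.56 for PAU, 0.37 for hypoxic genes, −0.51 for alpha-specific genes and −0.15 for mating pheromone genes, with the calls kept, and the calls of ergosterol synthesis (0.054), DNA damage (0.12), osmotic stress (−0.16) and thiamine (0.20) ended. Leaving out FLO1 microgravity replicate 2 gave 3.33 for PAU, 1.56 for hypoxic genes, 0.92 for ergosterol, 0.64 for thiamine, 0.44 for DNA damage, −0.76 for osmotic stress and −0.54 for mating pheromone genes. Calls also ended without FLO1 microgravity replicate 2 (fatty acid synthesis −0.34), FLO1 ground replicate 1 (osmotic stress −0.37), FLO8 microgravity replicate 2 (cell wall integrity 0.28, osmotic stress −0.17, thiamine 0.48) and FLO8 microgravity replicate 3 (fatty acid synthesis −0.22).

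Probe sets with no gene name, which no comparison above used, gave a signal in 5 comparisons; 404 of them lay above the S. pombe background and were adjusted among themselves. In wild type 3 were lower in flight, and 28 had an unadjusted p under 0.05. The largest of the 3 changes fell by 1.79 (SE 0.34, adjusted p = 0.0196). In the FLO1 strain 1 was lower (−1.07, SE 0.20, adjusted p = 0.0321), with 45 at an unadjusted p under 0.05. Averaged over strains 5 changed, 1 higher and 4 lower, with 62 at an unadjusted p under 0.05. Between the FLO1 strain and wild type 1 probe set was higher on the ground and 1 in flight. It was the same reporter probe set, RPTR-Sc-AJ002682-1_s_at, with adjusted p of 1.32e-18 and 5.23e-18. Its lowest value on the 5 arrays of the FLO1 strain was 13.71, against at most 3.84 on the other 12. The latter lie below the background of 4.56, so no size of the difference is given. Leaving out single arrays was not run for these probe sets.

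Ribosomal protein transcripts were lower in flight in the group means of each strain, with a list mean of −0.54 (SE 0.16) averaged over strains. FLO8 microgravity replicate 2 went the other way, at 12.38 log2 against at most 12.34 on the ground arrays of its strain. Compression or normalization of bright probe sets is argued against by 10000 lists of genes matched on level, whose medians lay between −0.06 and 0.02 for the central 95%, against −0.52 for the ribosomal proteins. RNA degradation stays open, because the 3 prime minus 5 prime difference went with flight over the 17 arrays (r = 0.669). With it as a covariate the mean was −0.50 (SE 0.28), 92.4% of its size, with 124 of 128 members below 0, but no longer below 0 by 2 SE. A different time of growth also stays open, since 0 runs held both conditions, and lower ribosomal protein expression in flight may be a response to flight or to any other difference between the runs.

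The FLO8 probe set read lower on the arrays of the strain labelled FLO8, at most 8.31 on its 6 arrays and at least 8.85 on the other 11. Single arrays swapped with the other strains are argued against by FLO11, whose lowest level on those 6 arrays (11.24) lay 1.76 log2 above the highest elsewhere (9.48). A strain labelled wrongly as a whole stays open, because all 6 arrays would share it. A copy of FLO8 whose transcripts the probe set does not read also stays open, because the array has 1 FLO8 probe set. How the strain was built is not in the labels, and no biological explanation was tested.

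Flight arrays lay farther from their group means than ground arrays, by 0.269 log2. The permutation within strains gave p = 0.00125, but it kept the distances from the real group means for every assignment. Distances within a group also depend on each other, so this p cannot decide on chance assignment of the arrays. RNA degradation and array background as the whole cause are argued against by their lack of relation with the distance over the 17 arrays (rho = −0.093, permutation p = 0.724, and rho = 0.065, permutation p = 0.804; adjusted p = 0.804 for both). After correction for each, the difference was 0.237 (exact p = 7.50e-04) and 0.153 (exact p = 0.00200), with the same limit on these permutation p-values. Among the 8 flight arrays rho was 0.333 and 0.539, so a part from either stays open. The conditions of growth and recovery in orbit were not tested, and they may add to the spread.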

How the results depend on the processing

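Leaving out the 4 flight arrays that stand apart was chosen after the data were seen, as was the average over strains. The number of arrays limits every count: with 3 or 2 flight arrays in a strain, 1 array can move many calls. Without the 4 arrays the FLO1 strain and the strain labelled FLO8 keep 1 flight array each, assumed to vary like the other groups. The shared spread then comes mostly from ground arrays, so the counts of that fit cannot be read as changes that the 4 arrays had hidden. In wild type the 4 include only WT microgravity replicate 3, and leaving out that array alone did not raise the count. Of the alternatives, all S. cerevisiae probe sets and a filter on dim probe sets left all 11 counts of changed genes within 1.5 times their value and kept all 176 values of named genes on their side of the test. The count of genes changed in all 3 strains was 0 by limma under every alternative run. Except where a construction is named, the cause of the changes below was not tested.

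A floor on dim values called 4 genes for flight in the FLO1 strain and 5 for FLO8 against wild type in flight. Quantile normalization called 1 for flight in the FLO1 strain, as did eBayes with trend and robust, which also called 1 for FLO8 against wild type in flight. Median centring called 13 for flight in wild type, and turned FLO9 there to −0.023. Array weights were estimated from these same arrays and ran from 0.087 (FLO8 microgravity replicate 2) to 8.35 (FLO8 ground replicate 2). Some weighted group means therefore rest mostly on 1 array, which limits the counts that follow. Array weights called 598, 0 and 748 genes for flight in wild type, the FLO1 strain and the strain labelled FLO8, 501 and 645 for FLO1 and FLO8 against wild type on the ground, 13 for FLO8 against wild type in flight, and 776 averaged over strains. They turned FLO1 for flight in wild type to 0.36, FLO10 and FLO11 for flight in the strain labelled FLO8 to 0.0047 and −0.26, FLO8 in the FLO1 strain on the ground to −0.0003 and FLO11 there in flight to −0.16, and FLO10 for FLO8 against wild type in flight to 0.011. With only the arrays compared, which leaves fewer arrays to estimate the variance, the counts were 0 and 0 for flight in wild type and the FLO1 strain, 9 and 0 for FLO8 against wild type on the ground and in flight, and 1 for FLO1 against wild type in flight. An absolute log2 fold change of at least 1 left 12 genes averaged over strains, by construction.

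With the replicate number as a block the counts were 3 and 0 for flight in wild type and the FLO1 strain, and 127 averaged over strains. The numbers gave no clear pairing of the arrays: of 40 pairs of arrays with the same number, 17 correlated above 0.1 (range −0.51 to 0.64). Counted by array, 8 correlated best with their own number. Whether the numbers mark a pairing was not tested. With the 3 prime minus 5 prime covariate, which widens the errors because it goes with flight, 1, 0 and 0 genes were called for flight in wild type, in the FLO1 strain and averaged over strains, and 1 for FLO8 against wild type in flight. It turned FLO1 and FLO9 for flight in wild type to 0.0077 and −0.039, STE3 and FLO9 in the FLO1 strain to 0.19 and −0.11, FLO8 for FLO1 against wild type in flight to 0.064, the mating pheromone list for flight in the FLO1 strain to 0.098 and the osmotic stress list for the response of FLO1 against FLO8 to 0.039. Without the 4 arrays that stand apart, 464 and 5 genes were called for flight in wild type and the FLO1 strain, 20 and 0 for FLO8 against wild type on the ground and in flight, and 1021 averaged over strains. This turned FLO1 in wild type to 0.32, FLO10 in the FLO1 strain to 0.17, FLO9, FLO10 and FLO11 in the strain labelled FLO8 to 0.044, 0.20 and −0.081, and FLO10 for FLO8 against wild type in flight to 0.041. It turned the lists of mating pheromone genes for flight in the FLO1 strain to 0.0036, of thiamine, DNA replication and DNA damage for FLO1 against wild type in flight to −0.036, −0.023 and −0.025, of methionine for FLO8 against wild type in flight to −0.093, and of osmotic stress for the response of FLO1 against FLO8 to 0.12.

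Leaving out 1 array at a time moved the counts for flight between 1 and 14 in wild type, 0 and 510 in the FLO1 strain, and 0 and 1 in the strain labelled FLO8. They ran from 2 to 396 for FLO1 and 1 to 32 for FLO8 against wild type in flight, and from 56 (without FLO1 ground replicate 1) to 512 averaged over strains. For the response of FLO1 they ran from 0 to 163 against wild type and from 0 to 135 against FLO8. The highest of these in wild type came without WT ground replicate 3, in the strain labelled FLO8 without FLO8 microgravity replicate 2, for FLO8 against wild type without FLO8 microgravity replicate 1, and in the others without FLO1 microgravity replicate 2. Genes that did not pass the test changed sign. For flight in wild type, FLO1 ran from −0.21 to 0.32, FLO9 from −0.13 to 0.20 and FLO10 from −0.13 to 0.37. In the FLO1 strain, FLO10 ran from −0.26 to 0.17 and FLO11 from −0.29 to 0.64, and in the strain labelled FLO8, FLO1 ran from −0.68 to 0.17, FLO9 from −0.34 to 0.095 and FLO11 from −0.22 to 0.54. For FLO1 against wild type, FLO8 ran from −0.010 to 0.18 on the ground and from −0.31 to 0.045 in flight, where FLO10 ran from −0.042 to 0.46 and FLO11 from −0.33 to 0.60. FLO10 for FLO8 against wild type on the ground ran from −0.018 to 0.36.

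Some lists changed sign without 1 array. The mating pheromone list for flight in the FLO1 strain ran from −0.38 to 0.0036 (without FLO1 microgravity replicate 1), ribosome biogenesis in the strain labelled FLO8 from −0.71 to 0.15 (without FLO8 microgravity replicate 3), and the proteasome for FLO1 against wild type on the ground from −0.17 to 0.0031 (without WT ground replicate 3). For FLO1 against wild type in flight, without FLO1 microgravity replicate 1, heat shock genes stood at 0.056 (lowest −0.41), glyoxylate genes at 0.018 (lowest −0.86), DNA replication genes at −0.078 (highest 0.32) and DNA damage genes at −0.0076 (highest 0.31). For FLO8 against wild type in flight, ribosomal proteins ran from −0.054 to 0.42, amino acid genes from −0.065 to 0.22 and methionine genes from −0.025 to 0.40, each lowest without FLO8 microgravity replicate 2. Ribosome biogenesis genes ran there from −0.67 to 0.20 (without FLO8 microgravity replicate 3). Trehalose and glycogen genes for the response of FLO1 against wild type ran from −0.54 to 0.050 (without FLO1 microgravity replicate 1).

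Of 120 list calls, 116 were kept under median centring, 110 under quantile normalization, 112 with the block, 89 with the covariate, 78 without the 4 arrays, 11 with fry and 0 with an estimated correlation. Of the 176 values of named genes, 173 were kept with each of the alternatives quantile normalization, median centring, and eBayes with trend and robust, 162 with the block and 130 with the covariate. Array weights kept 126, while 41 newly passed, 3 no longer passed and 6 changed sign.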

Other observations

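The permutation of list means and the fit without 4 arrays were chosen after the results were seen. By exact permutation of flight and ground within strains, 14 of 45 lists had an unadjusted p under 0.05 and 1 passed after adjustment. This permutation does not compare a list with other genes. The median difference over all genes tested was itself 0.030 averaged over strains, so small positive list means can carry that shift. Some lists missed the adjusted threshold of this exact permutation, such as a-specific genes (mean −0.26, p = 0.00500, adjusted p = 0.0563), hexose transporters and glucose sensing (mean 0.32, p = 0.00775, adjusted p = 0.0579), regulators of filamentous growth (mean 0.11, p = 0.0138, adjusted p = 0.0773) and the mitochondrial ribosome (mean 0.082, p = 0.0168, adjusted p = 0.0838). AGA2, the binding subunit of a-agglutinin, fell by 0.87 averaged over strains (SE 0.18, adjusted p = 0.0224). The 18 meiosis genes, which include HOP1, had a mean of 0.14 (exact permutation p = 0.0375, adjusted p = 0.122), and fry called them at an adjusted p of 0.0143 where camera did not (adjusted p = 0.111). HTB2, a histone H2B gene, fell by 0.74 averaged over strains (SE 0.09, adjusted p = 7.21e-04), though the histone list was not called by camera (mean −0.12; fry adjusted p = 0.0742).

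Markers of the strains were read in each group. URA3 and LYS2 lay between 3.32 and 3.86 log2 in all 6 group means, below the S. pombe background of 4.56, and LEU2 between 5.03 and 5.28. HIS3 lay between 9.84 and 10.19, and MET17, a sulfur assimilation gene, between 10.65 and 11.77. MET17 stood at 10.67 ± 0.15 (SD, n = 3) on the ground and 11.77 ± 0.22 (n = 2) in flight in the FLO1 strain. STE3, a receptor of alpha cells, lay between 9.57 and 10.67, and STE2, the receptor of a cells, between 7.42 and 8.19. Other genes specific to a cells were not uniformly low. MFA1 lay between 9.43 and 10.05, MFA2 between 8.46 and 9.83 and STE6 between 8.43 and 9.01, while BAR1, AGA2 and ASG7 reached at most 7.54.

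Other splits of the same arrays were refitted for the comparisons with at least 3 arrays in each group and for the average over strains, which sets 8 flight arrays against 9 ground arrays. In the latter, flight and ground were exchanged within each strain, so that each split kept 2 flight arrays for the FLO1 strain. For the average over strains, 1 of 100 splits, the real one, called as many genes (235 against a highest of 4 in the others). This argues against chance assignment of these arrays to flight and ground, for a comparison chosen after the data were seen. It cannot tell flight from another difference between the runs, or cover chance between cultures if replicates share one. For the difference in response between the strain labelled FLO8 and wild type, 100 of 100 splits called as many as the real 0, with a highest of 128. Every split calls at least 0, so this share says nothing about chance. The other comparisons have 10 splits, too few for a share under 0.05. For flight in wild type 1 of 10 called as many genes (8, highest other 0), and for flight in the strain labelled FLO8, 10 did (0, highest other 1), which again says nothing. On the ground it was 1 for FLO1 against wild type (2, highest other 0) and 1 for FLO8 against wild type (2, highest other 0). For FLO8 against wild type in flight 3 of 10 splits called as many as the real 2. The highest, 412 genes, set WT replicate 1 and FLO8 replicates 1 and 3 apart from the other flight arrays of the 2 strains, and 231 were called between WT replicates 1 and 2 with FLO8 replicate 1 and the rest. Splits that call so many more genes point to a structure among the flight arrays that their strain does not give.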
